A study of Mus musculus with 6 samples.

How the data were processed

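Messenger RNA was measured in 6 libraries of C2C12 cells, a clonal mouse myoblast line that can fuse into myotubes and that the labels call myocytes. The series sets 3 libraries of cells given 5-fluorouracil (5-FU) at 5 µg per L for 24 hours against 3 libraries of cells given phosphate-buffered saline (PBS). The titles name C2C12 for all 6 libraries, while the cell line field of 5-FU replicates 2 and 3 ends in other digits, and the titles were followed. Per the labels' protocols, total RNA was extracted with Trizol, enriched for mRNA, fragmented and made into cDNA libraries with a NEBNext Ultra RNA kit, and no step that marks the strand is described. StringTie 1.3.1 is named in the submitters' processing notes without a role. The aligner, the counting tool, the genome build and the annotation release are not given in the sources used here, so genes are identified by symbol and Ensembl identifier and no coordinates are printed.

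Per the file headers, the deposited table of 21899 genes gives an estimated count and a TPM value, an abundance scaled by transcript length and library total, for each gene and library. The deposited estimated counts are not normalized, and between 7.31% and 8.04% of the values of a library are not whole numbers (tolerance 0.005), as happens when a read is divided between genes or transcripts. The TPM values were made by the authors and add up to the same total over the listed genes in each library. The authors also deposited a table of 186 genes with group means in TPM, the log2 ratio of the 5-FU mean over the PBS mean, a p-value and an FDR per gene; the test behind that p-value is not stated. Every gene in that table has an absolute log2 ratio of at least 0.585 and an unadjusted p of at most 0.0495, and its FDR reaches 0.353. A mean TPM of 0 is written as 0.001 there, in 4 genes.

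The estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Of the 15909 genes with a count in any library, 12135 passed filterByExpr (at least 10 counts, scaled to the library sizes, in at least 3 libraries and 15 in total) and were tested. Libraries were scaled with TMM factors, which lay between 0.995 and 1.01. A quasi-likelihood F test compared 5-FU with PBS in both directions, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. A second count added an absolute log2 fold change of at least 1. The standard error of a log2 fold change was taken as its size divided by the square root of F. Values per group are counts scaled by library size (CPM) with the SD over 3 libraries. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these 6 libraries only.

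The lists and rules in this paragraph were fixed before the data were examined. Named genes were the 10 largest rises and the 10 largest falls among called genes that had a proper symbol, a mean of at least 1 CPM and groups that did not overlap; up to 4 called members of each gene list, by size of change, or with none called the member with the lowest p; and 18 genes named in advance whatever their result (Tyms, Umps, Dpyd, Upp1, Tk1, Rrm2, Cdkn1a, Mdm2, Cpt1a, Fasn, Srebf1, Pnpla2, Cd36, Ppargc1a, Pdk4, Myod1, Myog and Fbxo32). Of the called list members that this rule takes, 2 were left unnamed but stay in all counts. The 30 gene lists came from textbook knowledge of muscle cells, fluoropyrimidines, lipid metabolism, stress responses and other cell types, and 6 of their 927 symbols were not matched. The 27 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, against all other tested genes, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and fry were run beside it. Members were also counted with p-values adjusted over the list alone.

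Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size alone, no filter on low counts, a mean of at least 5 CPM, an adjusted p under 0.01, glmTreat against a fold of 1.2, the replicate number as a block, and leaving out each library in turn. Alternatives on FPKM, set in advance, were not run because the files give TPM. Chosen after seeing the data were limma with a trend on log2 TPM, with pseudocounts of 1 and 0.1, with genes of a mean of at least 1 TPM or without that filter, and an edgeR fit with offsets that remove smooth trends of each library with transcript length and GC content (GENCODE M21 transcripts, which 99.9% of tested genes matched). Also chosen after seeing the data were 3 further lists (aryl hydrocarbon receptor targets, circadian clock, actin cytoskeleton) and an enrichment of called genes in the pathway and process terms that the deposited table gives for each gene, by a one-sided Fisher's exact test against the annotated genes tested, for terms with 10 to 500 members.

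The edgeR step was tested on simulated data with the means and library sizes of these libraries, for 12135 genes, of which 12079 passed the filter. Simulated genes varied independently and carried no trends with transcript length, so the shares below may not hold for the real libraries. At a 1.2-fold change 48% of changed genes were called, at 1.3-fold 54%, at 1.5-fold 74% and at 2-fold 94%, and 3 of 11905 unchanged genes were called. Library totals lay between about 19583300 and 23016700 estimated counts, so that 3 counts in a library amount to between 0.130 and 0.153 CPM; these floors cover counting error only.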

Results

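Gene expression was measured by sequencing mRNA from C2C12 mouse myoblasts that were given PBS or were kept for 24 hours with 5-FU. The sample labels give a time for the 5-FU libraries only. 5-FU is a pyrimidine analogue that blocks thymidylate synthase and is built into RNA and DNA. The dose of 5 µg per L stood for metronomic treatment, in which a drug is given at a low, sustained level. Capecitabine, named in the series title beside lipid metabolism, is an oral precursor of 5-FU. Each group held 3 libraries. In replicate order, the PBS libraries held about 21054500, 22312700 and 20614200 estimated counts and the 5-FU libraries about 23016700, 19583300 and 21417700. Mitochondrially encoded genes took between 2.43% and 2.75% of the counts of a library. Libraries of the same group correlated at a Pearson's r of 0.994 to 0.995 across genes (log2 CPM; genes are not independent replicates), and the first principal component, with 37.4% of the variance, separated the groups.

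The only comparison of the design asked how gene expression in these muscle cells differed between 5-FU and PBS. In the 5-FU libraries the genes of the integrated stress response, the ATF4-driven programme of amino acid supply, were lower: 21 of 29 fell and none rose. Among them Atf3 went down from 31.3 ± 0.97 to 12.7 ± 1.1 CPM and Chac1 from 65.4 ± 5.1 to 29.6 ± 1.6 CPM (mean ± SD, n = 3). Targets of p53, the transcription factor of the DNA damage response, were mostly higher: 15 of 40 rose and 2 fell, with Cdkn1a, the cell cycle inhibitor p21, up from 444 ± 14 to 604 ± 58 CPM. Of 27 genes of cholesterol synthesis and uptake 11 fell and none rose, led by Idi1, Tm7sf2, Fdps and Acat2, and 7 and 6 of these calls were kept without PBS replicates 1 and 2. Without PBS replicate 2, 15 of the 21 stress response calls and 12 of the 17 p53 calls were kept. With an estimated correlation the list tests gave adjusted p = 0.0673, 0.0673 and 0.110 for the stress response, p53 and cholesterol lists. Among 44 genes of DNA replication edgeR called none and DESeq2 called 1. Most changes were small, with a median absolute log2 fold change of 0.30 among the called genes.

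edgeR's quasi-likelihood test called 866 of 12135 genes at an adjusted p under 0.05, 470 higher and 396 lower in 5-FU. In all 866 the 3 libraries of one group lay above the 3 of the other, as they did in 3552 of the tested genes (29.3%, where chance gives 10%). Only 20 called genes changed at least 2-fold, 12 upwards and 8 downwards. There were 34 without the filter on low counts, 3 at a mean of at least 5 CPM, 7 by DESeq2, 10 without PBS replicate 1 and 7 without PBS replicate 2. With limma on log2(TPM + 1), 528 genes were called and 64.8% of them were higher, against 54.3% with the counts. Without PBS replicate 2 the number called was 249, without PBS replicate 1 it was 498, without PBS replicate 3 it was 475, without 5-FU replicate 2 it was 499 and without 5-FU replicate 3 it was 491. The balance turned without PBS replicate 3, with 45.7% higher, without 5-FU replicate 3, with 49.9%, and at an adjusted p under 0.01, with 112 higher and 127 lower. Of the 866 calls, 226 were kept in all 6 refits that left out 1 library.

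**Figure D1:**
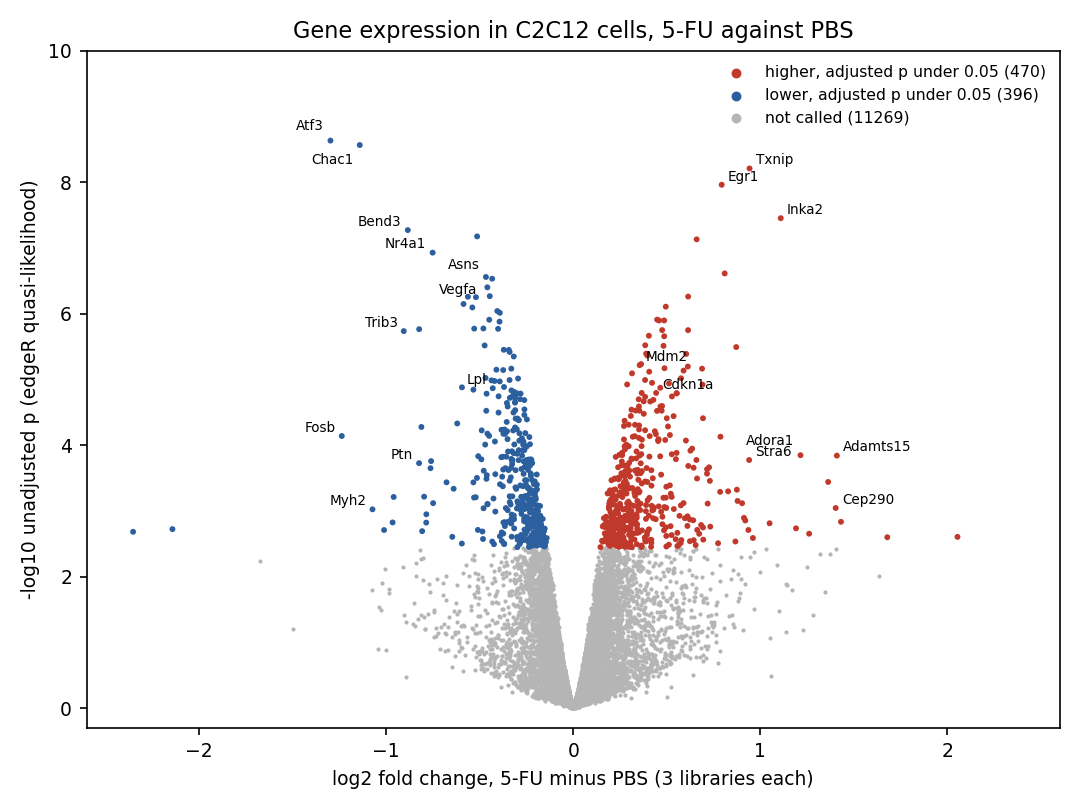
Log2 fold change (5-FU minus PBS, horizontal axis) of 12135 genes against the -log10 of the unadjusted edgeR p (vertical axis), with the 470 genes called higher in red, the 396 called lower in blue and genes not called in grey. Selected genes are named, and Atf3, Chac1, Txnip, Egr1 and Inka2 lie highest.

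The largest falls were those of Atf3 (ENSMUSG00000026628; log2 fold change -1.30, SE 0.077, edgeR adjusted p = 1.65e-05), Fosb (-1.24), Chac1 (ENSMUSG00000027313; -1.14), Myh2 (-1.07), Elovl7 (-1.01), Col8a2 (-0.97), Rec114 (-0.96), Trib3 (-0.91), Bend3 (-0.88) and Ptn (-0.82). Atf3 and Trib3 encode stress-induced regulators, Chac1 an enzyme that degrades glutathione, and Myh2 the myosin heavy chain of fast 2A fibres. The largest rises were those of Adamts15 (ENSMUSG00000033453; 1.41, SE 0.25, edgeR adjusted p = 0.00856), Cep290 (1.40), Ifit3 (1.26), Adora1 (1.21), Mab21l3 (1.19), Inka2 (ENSMUSG00000048458; 1.11), Slco4a1 (0.96), Txnip (ENSMUSG00000038393; 0.94), Stra6 (0.94) and Zfp930 (0.94). Txnip, which encodes a glucose-responsive arrestin that limits glucose uptake, rose from 39.4 ± 1.8 to 75.7 ± 5.0 CPM (n = 3; edgeR adjusted p = 2.50e-05). Of these 20 genes, Atf3, Fosb, Chac1, Trib3, Bend3, Adamts15, Inka2, Txnip and Stra6 were called in each of the 6 refits without 1 library, and the other 11 lost their call in at least 1 of them. Several of the 20 lay near the floor, such as Mab21l3 at 0.61 and 1.42 CPM, and Cep290, Adora1, Ifit3, Myh2 and Rec114 had counts that were not whole numbers.

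The list test with its preset correlation called 9 of 27 lists, 2 higher and 7 lower. With an estimated correlation camera called 0, with 8 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0673, while fry, which asks only whether a list's genes move one way, called 9, of which 8 were called by camera too. The estimated correlation was below the preset 0.01 for the p53 (-0.0197), endoplasmic reticulum chaperone (-0.0397) and glycolysis (-0.0103) lists. Their higher p-values with this setting therefore did not come from a higher correlation. For the other lists called with the preset it was higher, from 0.0118 for fatty acid synthesis to 0.426 for NRF2. Other splits of the 6 libraries into 3 and 3 gave up to 11 lists by camera with the preset correlation. The camera p-values are therefore read with caution and beside the counts of called members. Fry called at most 1 list in the other splits, but these mix both groups, so that a group difference adds to their spread.

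**Figure D2:**
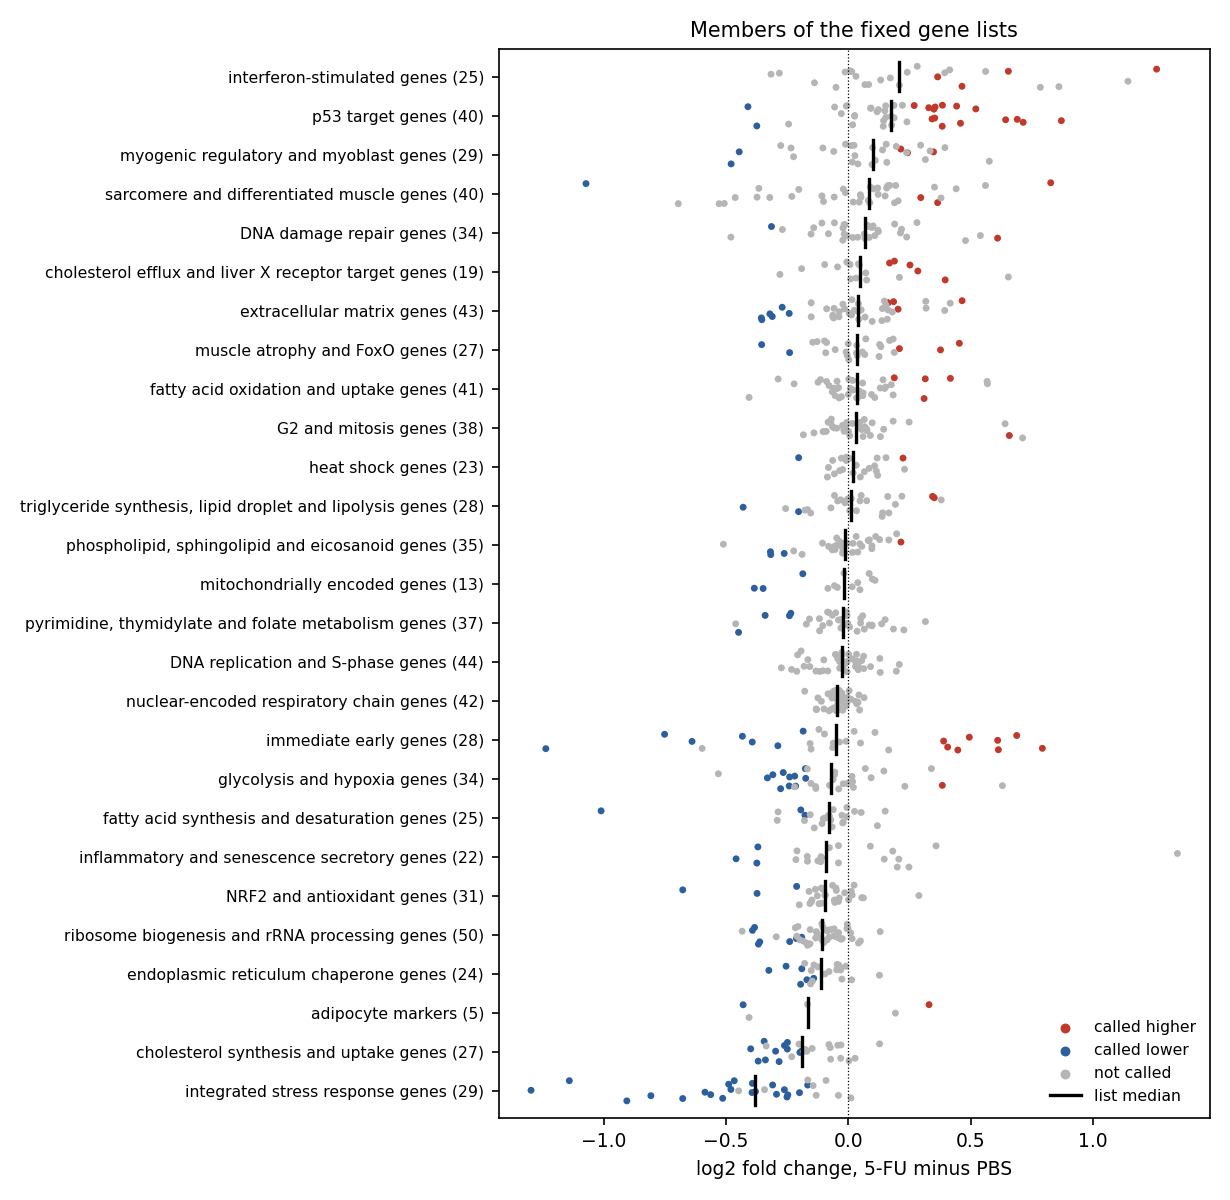
Log2 fold change (5-FU minus PBS, horizontal axis) of each tested member of the 27 fixed gene lists with at least 5 tested members, whose number stands in parentheses. Red and blue points were called higher and lower by edgeR, grey points were not called and black bars are list medians, which run from -0.38 for the integrated stress response to 0.21 for interferon-stimulated genes.

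Within the integrated stress response list 28 of 29 members had negative values (median log2 fold change -0.38; camera adjusted p = 1.63e-19, and adjusted p = 0.0673 with an estimated correlation). Adjusted over the list alone, 24 were lower. Of the 21 calls 15 were kept in all 6 refits without 1 library, and the fewest, 15, were kept without PBS replicate 2. Atf4 itself (ENSMUSG00000042406) fell from 489 ± 12 to 373 ± 10 CPM, and others fell with it. They include the amino acid transporters Slc7a5 (-0.51), Slc7a1 (-0.56) and Slc7a11 (-0.68), the asparagine synthetase Asns (-0.47), the serine synthesis enzymes Psat1 (-0.39) and Phgdh (-0.25), the cystathionine enzyme Cth (-0.81) and the tRNA synthetases Gars (-0.26), Aars (-0.20) and Sars (-0.17). Cth lost its call in 4 of the 6 refits without 1 library and Slc7a11 in 2. In the list of endoplasmic reticulum chaperones 6 of 24 fell, the largest falls being those of Sec61b (-0.32), Sdf2l1 (-0.25), Hspa5 (-0.19) and Herpud1 (-0.19). Of these Hspa5 encodes a chaperone, Sec61b a subunit of the translocation channel and Herpud1 a protein of the degradation pathway. Adjusted over the list alone, 9 were lower (camera adjusted p = 1.07e-04, and adjusted p = 0.0817 with an estimated correlation). None of these 6 calls was kept without PBS replicate 2, and 3, 1, 3, 2 and 2 were kept without PBS replicates 1 and 3 and 5-FU replicates 1, 2 and 3. Heat shock genes gave 1 call in each direction among 23, Dnajb1 (0.22) and Hspd1 (-0.20). There were 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.511). Neither heat shock call was kept without PBS replicate 1 or 2, and 1 was kept without PBS replicate 3 and without each 5-FU replicate.

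Among the 40 p53 targets, Psrc1 (0.87), Pidd1 (0.72), Trp53inp1 (0.69) and Polk (0.64) rose most, and Mdm2, the p53 ubiquitin ligase, rose from 78.4 ± 2.9 to 100.3 ± 0.90 CPM (edgeR adjusted p = 0.00150). Zmat3 (0.46), Cdkn1a (0.44), Ak1 (0.38), Btg2 (0.38), Ccng1 (0.35) and Phlda3 (0.35) rose as well. The 2 members that fell, Sesn2 (-0.41) and Plk3 (-0.37), are also known as stress-induced genes outside p53, Sesn2 through ATF4. Adjusted over the list alone, 20 were higher and 2 lower (median 0.18; camera adjusted p = 1.80e-07, and adjusted p = 0.0673 with an estimated correlation). Cdkn1a had counts that were not whole numbers. Of the 17 calls 12 were kept in all 6 refits without 1 library, the fewest being kept without PBS replicate 2. Pidd1 and Polk each lost their call in 1 refit. Of 34 repair genes, the damage kinase Atm rose (0.61) and the glycosylase Tdg fell (-0.31), with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.353). Atm was not called by DESeq2 (adjusted p = 0.0848) or in any refit without 1 library except that without 5-FU replicate 1, so that without PBS replicates 1, 2 and 3 and 5-FU replicates 2 and 3 only Tdg was called.

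**Figure D3:**
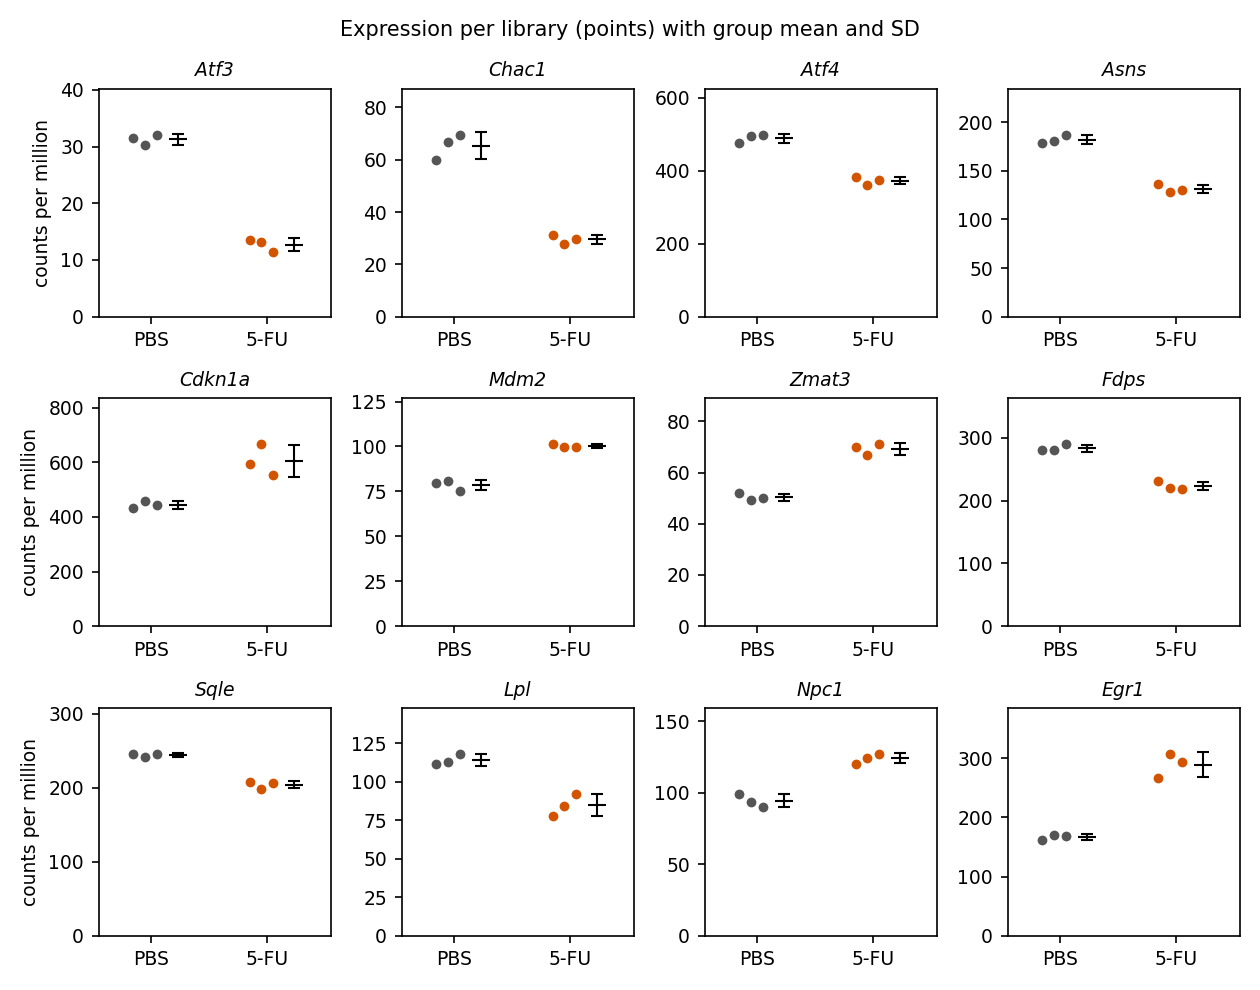
CPM (vertical axes, each from 0) of 12 genes in the 3 PBS and 3 5-FU libraries, as points, with the group mean and SD beside them. The groups do not overlap in any of the 12 genes, with Atf3, Chac1, Atf4, Asns, Fdps, Sqle and Lpl lower and Cdkn1a, Mdm2, Zmat3, Npc1 and Egr1 higher in 5-FU.

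No gene of 44 in the list of DNA replication and S phase was called by edgeR or limma-voom, 7 had an unadjusted p under 0.05, and DESeq2 called 1. Pcna, the clamp of the replication fork, gave the lowest p (-0.17, edgeR adjusted p = 0.0742). None was called adjusted over the list alone (camera adjusted p = 0.287), and the list was called lower without 5-FU replicate 3 (adjusted p = 0.0427). Of 38 genes of G2 and mitosis, Mki67, a proliferation marker, was the only one called by edgeR (0.66), while DESeq2 called 4, and 5 were higher adjusted over the list alone (camera adjusted p = 0.476). The Mki67 call ended without PBS replicate 2. Tyms, which encodes the thymidylate synthase that 5-FU inhibits, stood at 51.4 ± 0.92 and 52.7 ± 4.3 CPM (log2 fold change 0.036, SE 0.062). Not called either were Umps (-0.0077), Tk1 (-0.030), Rrm2 (0.097) and Upp1 (-0.46, SE 0.16, edgeR adjusted p = 0.108). Dpyd, the enzyme that breaks down 5-FU, was too low to test, with 11 counts over the PBS libraries and 14 over the 5-FU libraries. In the list of pyrimidine, thymidylate and folate metabolism 4 of 37 fell, the folate enzymes Mthfd2 (-0.45) and Shmt2 (-0.23) and the pyrimidine kinases Uck2 (-0.34) and Cmpk1 (-0.24). Of these, 2 were kept without PBS replicate 2. There were 1 higher and 5 lower members adjusted over the list alone (camera adjusted p = 0.287; called lower without 5-FU replicate 1, adjusted p = 0.0304). Ribosome biogenesis genes were lower as a list, with 7 of 50 down, led by Dkc1 (-0.39), Ppan (-0.38), Tsr1 (-0.37) and Wdr43 (-0.36). Members lower when adjusted over the list alone numbered 12 (camera adjusted p = 4.51e-07, and adjusted p = 0.110 with an estimated correlation). Of those 7 calls 3, 2 and 3 were kept without PBS replicates 1, 2 and 3, and 3 and 4 without 5-FU replicates 2 and 3.

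In cholesterol synthesis and uptake, Idi1 (-0.40), Tm7sf2 (-0.37), Fdps (-0.34), Acat2 (-0.34), Msmo1 (-0.30), Lss (-0.28), Sqle (-0.26), Insig1 (-0.25), Nsdhl (-0.25), Cyp51 (-0.20) and Hmgcs1 (-0.19) fell. Adjusted over the list alone, 1 was higher and 16 were lower (median -0.19; camera adjusted p = 4.03e-08, and adjusted p = 0.110 with an estimated correlation). Of these 11 calls 7 were kept without PBS replicate 1 and 6 without PBS replicate 2. In the list of cholesterol efflux and liver X receptor targets 5 of 19 rose and none fell. Npc1, which moves cholesterol out of lysosomes, rose from 94.3 ± 4.6 to 124 ± 3.5 CPM, and the transporter genes Abca3 (0.28), Abca2 (0.25), Abca7 (0.19) and Pltp (0.17) rose by less. There were 5 higher adjusted over the list alone, and the list was not called (camera adjusted p = 0.0547), except without 5-FU replicate 1 (adjusted p = 0.0304), without the filter (adjusted p = 0.0468) or at a mean of at least 5 CPM (adjusted p = 0.0254). Without PBS replicates 1, 2 and 3 there remained 3, 1 and 2 of these 5 calls, and without 5-FU replicates 1, 2 and 3 there remained 2, 3 and 1. After a correction for transcript length and GC content 3 of the 5 were kept. Fatty acid synthesis and desaturation gave 3 falls among 25, the elongase Elovl7, Fads3 (-0.19) and Hsd17b12 (-0.18). There were 7 lower members adjusted over the list alone (camera adjusted p = 0.00249, and adjusted p = 0.110 with an estimated correlation). None of the 3 calls was kept without PBS replicate 2, 1 without PBS replicate 1 and 1 without each 5-FU replicate. The fatty acid synthase gene Fasn (0.12, edgeR adjusted p = 0.202) and the lipogenic regulator Srebf1 (-0.0055, edgeR adjusted p = 0.955) were not called.

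In fatty acid oxidation and uptake 4 of 41 rose, Cpt1c (0.42), Ucp2 (0.31), Pdk4 (0.31) and Acaa2 (0.19), and none fell. There were 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.287). Of the 4 calls 2 were kept without PBS replicate 1, 1 without PBS replicate 2, and 2 each without 5-FU replicates 1 and 3. Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, stood at 184 ± 13 and 208 ± 16 CPM (0.18, edgeR adjusted p = 0.120), and Cd36 (0.13) and Pnpla2 (0.075), which encode a fatty acid transporter and a triglyceride lipase, were not called. Ppargc1a, a regulator of mitochondrial genes, had 13 counts in each group and was not tested. Of 28 genes of triglycerides and lipid droplets, the droplet coat gene Plin2 (0.34) and Lpin1 (0.35) rose, and the lipoprotein lipase Lpl (-0.43, SE 0.059, edgeR adjusted p = 0.00223) and Lpin3 (-0.20) fell. There were 5 higher and 4 lower members adjusted over the list alone (camera adjusted p = 0.723). Phospholipid, sphingolipid and eicosanoid genes gave 1 rise, Pisd (0.22), and 3 falls, Pcyt2 (-0.32), Sphk1 (-0.32) and Sgms2 (-0.26), among 35, with the same numbers adjusted over the list alone (camera adjusted p = 0.623). Without PBS replicate 2 only Lpl kept its call among the triglyceride genes and 1 of 4 among the phospholipid genes. Without PBS replicate 1 and without 5-FU replicates 2 and 3 each group kept 2, and without 5-FU replicate 1 the triglyceride genes kept 2.

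Glycolysis and hypoxia genes were lower, with 10 of 34 down, among them the glucose transporter Slc2a1 (-0.28), Hk2 (-0.33), Pdk1 (-0.31), Ndrg1 (-0.27) and Pfkl (-0.22), and 1 up, Eno2 (0.38). There were 2 higher and 14 lower members adjusted over the list alone (camera adjusted p = 0.00347, and adjusted p = 0.110 with an estimated correlation). Of these 11 calls 7, 3 and 7 were kept without PBS replicates 1 and 2 and 5-FU replicate 3. NRF2 and antioxidant genes gave 3 falls among 31, Slc7a11, Osgin1 (-0.37) and Mt2 (-0.21), and the same 3 adjusted over the list alone (camera adjusted p = 0.00347, and adjusted p = 0.842 with an estimated correlation). None of the 3 was kept without PBS replicate 2, and 1 each without PBS replicates 1 and 3 and 5-FU replicates 2 and 3. DESeq2 called 5 of these genes. This list was not called without PBS replicate 3 (adjusted p = 0.0659), without 5-FU replicate 2 (adjusted p = 0.181), by fry (adjusted p = 0.325) or after the length and GC correction (adjusted p = 0.0660). Nuclear genes of the respiratory chain gave 0 calls among 42 by edgeR, DESeq2 and limma-voom, with 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Cox7c had the lowest p (-0.13, edgeR adjusted p = 0.175; camera adjusted p = 0.0612 for the list). The list was called lower without PBS replicate 1 (adjusted p = 0.00217) and without 5-FU replicate 1 (adjusted p = 0.00123). Of the 13 mitochondrially encoded genes mt-Atp8 (-0.38), mt-Nd3 (-0.35) and mt-Co3 (-0.19) fell, the same 3 adjusted over the list alone (camera adjusted p = 0.353), and none of them was called without PBS replicate 2. After the length and GC correction 1 of the 3 was kept. The list was called lower without 5-FU replicate 3 (adjusted p = 0.0376).

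Interferon-stimulated genes were higher, with 4 of 25 up, Ifit3 (1.26), Oasl2 (0.65), Xaf1 (0.46) and Stat2 (0.37), and 9 higher adjusted over the list alone (median 0.21; camera adjusted p = 2.70e-04, and adjusted p = 0.136 with an estimated correlation). Of the 4 calls 2, those of Xaf1 and Stat2, were kept in each of the 6 refits without 1 library. The 2 with the larger changes were low and less stable. Ifit3, at 0.67 and 1.64 CPM in PBS and 5-FU, lost its call in 5 refits and kept it without 5-FU replicate 3. Oasl2, at 1.95 and 3.08 CPM, lost its call in all 6. DESeq2 called 2 genes of this list. Immediate early genes split: 8 of 28 rose, led by Egr1 (from 167 ± 4.3 to 290 ± 21 CPM, edgeR adjusted p = 3.31e-05) and Egr2 (0.69), and 7 fell, led by Fosb and Nr4a1 (-0.75). There were 10 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.946). Of 22 inflammatory and senescence secretory genes 3 fell, among them Vegfa (-0.46) and Ccl2 (-0.37). Each refit without 1 library kept 2 of these calls and lost that of Ccl2, and DESeq2 called 2 genes of this list. Adjusted over the list alone 1 was higher and 5 were lower (camera adjusted p = 0.287; fry adjusted p = 0.0288; median -0.093 but mean 0.0092). The list of extracellular matrix genes, which also held the cytoskeletal genes Tagln and Acta2, gave 4 rises and 6 falls among 43. Fbln5 (0.47) led the rises. Among the falls were the matrix genes Timp3 (-0.36) and Tnc (-0.32), and also Tagln (-0.35) and Acta2 (-0.31). There were 11 higher and 6 lower members adjusted over the list alone (camera adjusted p = 0.623), and 6 of the 10 calls were kept without PBS replicate 2.

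Muscle genes showed no common direction. Of 29 myogenic regulators and myoblast genes 3 rose, among them Id1 (0.35) and Cdh15 (0.21), and Id2 (-0.48) and Sdc4 (-0.45) fell, with 12 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.125, 0.0376 without 5-FU replicate 3 and 0.0337 at a mean of at least 5 CPM). The calls kept were 3, 2 and 2 of 5 without PBS replicates 1, 2 and 3, and DESeq2 called 8. The myogenic regulators Myod1 (0.097, edgeR adjusted p = 0.155) and Myog were not called, the second at 259 ± 21 and 327 ± 72 CPM (0.33, edgeR adjusted p = 0.123). Of 40 sarcomere genes Ttn (0.83), Actn3 (0.37) and Ldb3 (0.30) rose and Myh2 fell, and 4 were higher and 1 lower adjusted over the list alone. The median was 0.085 while camera's direction was down (adjusted p = 0.946). The sarcomere list was called lower without 5-FU replicate 2 (adjusted p = 7.15e-04) and higher without 5-FU replicate 3 (adjusted p = 0.0360), and on log2(TPM + 1) Ttn was not called (0.30, adjusted p = 0.331). None of the 4 sarcomere calls was kept without PBS replicate 1, 1 each without PBS replicates 2 and 3 and 5-FU replicate 2, and 2 each without 5-FU replicates 1 and 3. DESeq2 and limma-voom each called 2 sarcomere genes. Among 27 atrophy and FoxO genes the transcription factors Foxo1 (0.45) and Foxo3 (0.38) and the ubiquitin ligase gene Cblb (0.21) rose, Eif4ebp1 (-0.35) and Bnip3 (-0.24) fell, and the atrophy ligase gene Fbxo32 was not called (-0.0091). There were 7 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.301). Of the 5 calls 3 were kept without PBS replicate 2 and as many without 5-FU replicate 3.

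Of the adipocyte markers Car3 (0.33) rose and Lpl fell among 5 tested, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.610). The leukocyte, endothelial and epithelial lists had 2, 2 and 4 tested members, none of them called by edgeR, DESeq2 or limma-voom or adjusted over the list alone, with 2 epithelial markers and no others at an unadjusted p under 0.05. Their lowest p-values were those of Cd68 (0.36), Vwf (0.75) and Krt14 (0.29). Summed over the list, adipocyte markers gave 232 ± 5.5 and 218 ± 9.8 CPM, leukocyte markers 15.3 ± 0.99 and 17.2 ± 3.3 CPM, endothelial markers 1.82 ± 0.18 and 2.77 ± 0.42 CPM and epithelial markers 49.6 ± 3.7 and 47.8 ± 6.0 CPM in PBS and 5-FU (n = 3; two-sided exact permutation p = 0.2, 0.5, 0.1 and 0.7, where 0.1 is the smallest possible).

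The authors' table of changed genes holds 142 higher and 44 lower genes, 74 of them at their FDR under 0.05. Of its 186 genes 165 were tested here, all 165 with the same direction, and 101 were called, among them Atf3 (the authors' log2 ratio -1.26), Chac1 (-1.10), Inka2 (1.14), Txnip (0.98) and Egr1 (0.84). Without PBS replicate 1 the number called was 54, and without PBS replicate 2 it was 43. Called here and absent from that table were 765 genes, of which 757 had an absolute log2 fold change smaller than any log2 ratio in that table.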

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

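The tests on TPM and the length and GC correction were chosen after the result was seen, and the other alternatives before. Of the 119 named genes tested, 101 were called. All 101 kept their direction in every alternative fit that tested them, and 25 were called in every such fit. An adjusted p under 0.01 and glmTreat were not applied to the named genes, only to the counts of genes called. The number called was 858 with DESeq2, 836 with limma-voom, 861 with RLE factors, 852 with upper-quartile factors, 908 with library size alone (63.7% higher), 1045 without the filter, 846 at a mean of at least 5 CPM and 1089 with the length and GC correction (741 shared). The labels name no link between replicates of the same number, and correlations of their deviations from the group means were -0.002, 0.087 and 0.132, not each the best for its library. The second principal component, with 18.9% of the variance, set both replicate 3 libraries (-13.1 and -11.2) apart from the others (4.0 to 9.0). Mitochondrial shares in replicates 1 to 3 were 2.43%, 2.62% and 2.75% in PBS and 2.43%, 2.69% and 2.75% in 5-FU. A link by replicate number therefore stays open. With the replicate block 1199 genes were called (853 shared). Tests on FPKM were not run. Depth limits the low genes: at a CPM of 0.130 to 0.153 a library holds 3 counts.

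On log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) without a filter, 528, 513 and 156 genes were called, 186, 179 and 68 of them lower, 88 higher in the last, and 6, 7 and 3 changed at least 2-fold. An adjusted p under 0.01 left 239 genes (112 higher, 127 lower, 8 at least 2-fold) and glmTreat 30 (16, 14 and 4), as a stricter bar must. DESeq2 gave 7 genes of at least 2-fold, no filter 34 and a mean of at least 5 CPM 3. Leaving out each library, with fewer samples, gave 249 to 656 genes, 125 to 382 higher, 124 to 274 lower, 7 to 23 at least 2-fold and 43 to 90 shared with the authors' table. The estimated correlation called 0 lists, and leaving out each library 8 to 13.

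Among the named genes and the lists, signs turned only where edgeR and camera had called nothing; called genes not named were not followed. On log2(TPM + 1), log2(TPM + 0.1) and without a filter Tk1 had 0.00813, 0.00818 and 0.00813, Fbxo32 0.0277, 0.0298 and 0.0277, Umps 0.0301, 0.0308 and 0.0301, Srebf1 0.0256, 0.0259 and 0.0256, and Tyms -0.0194, -0.0197 and -0.0194; Cd36 had -0.143 without a filter. With library size alone Fbxo32 had 0.00515, Umps 0.00673 and Srebf1 0.00886. Length and GC correction gave Umps 0.00604 and Fasn -0.0387. Without 1 library Tk1 ran from -0.0718 to 0.0318, Fbxo32 from -0.0714 to 0.0564, Umps from -0.0533 to 0.0280, Srebf1 from -0.0182 to 0.0134, Tyms from -0.0261 to 0.0904 and Cd36 from -0.124 to 0.311.

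Lists whose tested direction turned, with medians, were the sarcomere list (fry 0.0849, mean of at least 5 CPM 0.0860, no filter 0.0847, replicate block 0.0592) and the immediate early list (fry -0.0485, mean of at least 5 CPM -0.0181). With the length and GC correction the matrix list had -0.0391, the nuclear respiratory chain list 0.0126 and the mitochondrially encoded list 0.108, and without the filter adipocyte markers had 0.410. Without 1 library medians ran from -0.160 to 0.241 for sarcomere, -0.0538 to -0.00551 for immediate early, 0.00808 to 0.0596 for matrix, -0.112 to 0.0872 for mitochondrially encoded, -0.0274 to 0.0692 for mitosis, -0.0417 to 0.0214 for replication and 6.31e-05 to 0.0456 for triglyceride genes. The cause was not tested for any of these.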

Other observations

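The tests of the 3 added lists, of the annotation terms, of the length slopes, of admixed cells and of the splits by fry, and the length and GC correction, were chosen after the result was seen.

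Genes of the actin cytoskeleton, many of them targets of serum response factor, were lower in 5-FU: 12 of 21 fell and none rose. They include the smooth muscle genes Myl9 (-0.54), Cnn1 (-0.46), Tagln (-0.35) and Acta2 (-0.31), the tropomyosins Tpm4 (-0.37) and Tpm1 (-0.23), and Csrp1 (-0.33), Cnn2 (-0.31), Tagln2 (-0.25) and Zyx (-0.15). The abundant actins fell too, Actg1 by a log2 fold change of -0.31 and Actb from 4006 ± 48 to 3283 ± 188 CPM (mean ± SD, n = 3; edgeR adjusted p = 0.00540). All 12 calls were kept after the length and GC correction. Without 1 library between 9 of them (without PBS replicate 2, for example) and 11 (without 5-FU replicate 1) were kept. Tagln and Acta2 were also counted in the extracellular matrix list. The 3 lists of this paragraph were assembled after changed genes had been seen and adjusted over these 3 alone, so that their list tests describe the values and cannot serve as separate evidence. For actin they gave a camera adjusted p of 5.46e-11 (adjusted p = 0.0135 with an estimated correlation, fry adjusted p = 3.60e-04). Targets of the aryl hydrocarbon receptor were higher, with 4 of 8 up: Cyp1a1 (0.72), Ahrr (0.60), Aldh3a1 (0.58) and Cyp1b1 (0.25). Its camera adjusted p was 2.94e-04 (adjusted p = 0.0742 with an estimated correlation, fry adjusted p = 0.00994), which leaves a shared response of the receptor targets open. Without 5-FU replicate 1 and without 5-FU replicate 3, 2 of the 4 calls were kept. Of 18 clock genes 3 fell, Nr1d1 (-0.52), Nr1d2 (-0.33) and Cry2 (-0.33), and none rose (camera adjusted p = 0.0149, adjusted p = 0.0742 with an estimated correlation, fry adjusted p = 0.00508). Without PBS replicate 2 only 1 of these calls was kept, and without PBS replicate 1 and 5-FU replicates 2 and 3 there were 2. Of Dbp, Tef, Nr1d2 and Per3, which share the clock elements of Nr1d1, 1 was called lower, which argues against a shift in clock phase.

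Terms of the deposited annotation, tested on the same called genes, repeated some themes of the lists and gave some new ones. Their members overlap with those of the lists, so the repeated themes are no separate support. No interferon, ribosome biogenesis, fatty acid synthesis or antioxidant term was enriched. Among the higher genes, 8 of 2285 process terms and 5 of 315 pathway terms were enriched. Notch signaling held 13 called genes of 80 where 3.13 were expected (FDR 0.0138), among them the receptors Notch1 (0.53) and Notch3 (0.39), the ligand Dll1 (0.59) and the target genes Heyl (0.68) and Hey1 (0.48). Positive regulation of apoptosis held 29 of 284 (expected 11.1, FDR 0.00493), and the p53 pathway 11 of 66 (expected 2.64, FDR 0.00787). Among the lower genes 14 process and 5 pathway terms were enriched. Cholesterol biosynthesis held 9 of 26 (expected 0.867, FDR 1.01e-04), amino acid biosynthesis 8 of 22 (FDR 2.31e-04), neutral amino acid transport 6 of 16 (FDR 0.00261) and tRNA aminoacylation 7 of 33 (FDR 0.0201). The 4 called genes of 10 in polyamine biosynthesis were Odc1 (-0.17), Sms (-0.20), Azin1 (-0.29) and Azin2 (-0.33; FDR 0.0384). Translation held 26 of 272 (expected 9.07, FDR 7.72e-04), among them genes of ribosomal proteins such as Rps28 (-0.33) and Rpl38 (-0.25). After the length and GC correction 1 of the 8 process and 3 of the 5 pathway terms stayed enriched among the higher genes, and 10 of the 14 and 5 of the 5 among the lower genes. The Notch process term (FDR 0.0414), the p53 pathway (FDR 0.0254), cholesterol biosynthesis (FDR 0.00110), amino acid biosynthesis (FDR 0.00146), neutral amino acid transport (FDR 0.00146) and tRNA aminoacylation (FDR 0.00342) stayed enriched. Translation (FDR 0.161), polyamine biosynthesis (FDR 0.192), positive regulation of apoptosis (FDR 0.0759) and the Notch pathway term (FDR 0.135) did not.

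The fall of the stress response list was set against bias and culture. After the length and GC correction its median was -0.366, and 21 of 21 calls were kept, which argues against length or GC content as the whole cause. Less depleted medium in the 5-FU wells could also lower this list, and Arrdc4, which glucose induces together with Txnip, was to tell: it had 0.444 (SE 0.370, edgeR adjusted p = 0.498), at 0.585 and 0.799 CPM. Counts this low leave it open, so that an effect of 5-FU on this pathway and a difference in medium cannot be told apart.

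The rise of the p53 targets kept a median of 0.205 and 15 of 15 calls after the same correction, which argues against length or GC content as the whole cause. Admixed cells of another type stay open. Of the 8 leukocyte, endothelial and epithelial markers tested 0 were called higher (largest value 0.75, Vwf), which is few markers. The leukocyte, endothelial and epithelial sums were 15.3, 1.82 and 49.6 CPM in PBS and 17.2, 2.77 and 47.8 CPM in 5-FU. Cdkn1a rose from 444 to 604 CPM. These low sums gave no sign of a large share of these cell types, but cannot exclude a small share or other types. A response to 5-FU in these cells stays a hypothesis.

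Long transcripts were higher in 5-FU: 0.218% of tested genes of up to 1000 nt were called higher and 5.46% lower, against 5.81% and 1.42% of those over 8000 nt. The slope of log2 CPM on log2 transcript length was 0.00633, -0.0178 and -0.0479 in PBS replicates 1 to 3 and -0.0237, 0.0412 and 0.0419 in 5-FU replicates 1 to 3 (difference of means 0.0396, two-sided exact permutation p = 0.3). The lowest 5-FU slope minus the highest PBS slope gave -0.0301, as length bias of single libraries would give. A response of long genes to 5-FU smaller than this spread cannot be told apart from it with 3 libraries per group. With the correction 9 genes of up to 1000 nt were higher and 14 lower, and 36 and 32 over 8000 nt.

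The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixes both groups on each side, so a group difference shrinks in it and adds to its spread. Fewer calls and smaller medians there are therefore no separate support for the real split. The real split called 866 genes and the highest other split 1, so that 1 of 10 splits gave as many. For lists called by camera with the preset correlation 5 of 10 splits gave as many as the real 9, and the highest other gave 11; fry called 9 in the real split and at most 1 in the others. The stress response median of -0.379 compares with an absolute median of at most 0.143 in other splits, the p53 median of 0.176 with 0.0910, and the sarcomere median of 0.0849 with 0.379.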
